A study of Mus musculus with 18 samples.

How the data were processed

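Gene counts of 18 sequencing libraries were analysed, from immune cells of the aortas and carotid arteries of male and female Apoe-deficient mice with fluorescent reporters of Cx3cr1 and Cd11c. Per the labels' protocols, live CD45-positive cells of digested vessels were sorted by GFP and YFP into 4 subsets (GFP, n = 6; DP, n = 4; YFP, n = 5; DN, n = 3), RNA was extracted, and libraries were made with SMART-seq v4 (11 cycles of amplification) and Nextera XT kits and sequenced on an Illumina HiSeq instrument. Per the submitters' processing notes, TopHat 1.4.1, SAMtools and HTSeq 0.7.1 and the genome build mm10 were used. The annotation and the strand setting of the counting were not given in the sources used here, so reads of overlapping and antisense genes may be mixed, and genes with near-identical copies, such as Ear1, Ear2 and Ear6 or Hspa1a and Hspa1b, are uncertain where reads could fit several copies. The authors deposited whole-number counts per gene, not normalized, as 1 table of 23337 gene symbols by 18 libraries, and these deposited counts were used as they stood. All columns were matched to samples by name.

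Samples were grouped by the sorted subset in the labels. Total counts per library ranged from 289166 to 27742113. Reads carry no molecular identifiers, so counts are not independent molecules. No pair of libraries of a subset agreed within sampling noise (chi-square per degree of freedom of 16.66 at the least), so each was counted once. Detected genes were also counted after thinning all libraries to 280000 counts and, without YFP replicate 6, to 9700000 counts.

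Genes were tested with edgeR 4.0.16 in R 4.3.3, with filterByExpr by subset, TMM scaling, and the robust quasi-likelihood fit and test with 1 mean per subset over all 18 libraries. This left 17143 genes, with a common dispersion of 0.890. Each of the 6 pairs of subsets was compared, the interaction of both reporters was tested, and each subset was tested against the mean of the other 3. A gene counted as enriched in a subset when its fitted mean was also at least 1 log2 unit above each other subset. P-values were adjusted by Benjamini-Hochberg, with a threshold of 0.05, and standard errors of log2 fold changes were derived from the fold change and its F statistic. CPM values are counts relative to library sizes scaled by TMM, and errors of CPM are SD.

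Lists of marker and pathway genes, 36 in number with 627 entries, were fixed before the data were examined, as were the comparisons and most of the other settings tried. Of the entries, 617 matched a symbol in the table. Lists with at least 3 tested members were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over 216 tests of 36 lists in 6 comparisons, with camera at an estimated correlation and fry beside it. Members were also adjusted over the list alone. Of the called lists, the text describes the 6 with the smallest p in each comparison and those also called with an estimated correlation, with up to 3 members each. The dissociation list is also given for YFP and DP versus GFP, as are 4 lists outside this choice, of lipid uptake (YFP versus GFP), foamy macrophages (GFP versus DN), and classical monocytes and resident macrophages (DP versus GFP). This selection of lists was chosen after the data were seen. The lists of actin and motility, matrix proteases, and chemokine ligands and receptors are given together for the question of cell movement, also outside this choice. The foamy or TREM2-high macrophage list holds Itgax, the gene that drives the YFP reporter. List levels are means of log2(CPM + 1).

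Single genes were named by a rule fixed before the data were examined. For comparisons of GFP, DP and YFP it took the 10 with the largest log2 fold change in each direction past the threshold, with a mean of at least 20 CPM in the higher subset and every library of that subset above the median of the lower one, and for comparisons with DN 5 in each direction. For each subset's enriched genes it took the 8 with the largest difference. It skipped predicted genes, pseudogenes and receptor segments, and added Cx3cr1, Itgax, Apoe and members of the lists with the smallest p. Coordinates are from the GENCODE vM21 annotation of the mm10 assembly, matched by symbol, which held 20953 of the 23337 symbols and 99 of the 101 genes that these rules took, all but Chi3l3 and Emr4.

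The replicate numbers were checked for pairing by correlating deviations of same-numbered libraries from their subset means. For GFP and DN all 3 pairs were above 0.1 (0.66, 0.53 and 0.63). Libraries of different numbers correlated as well, such as GFP replicate 2 with DN replicate 1 (0.72) and GFP replicate 5 with DN replicate 6 (0.57). The correlations thus cannot tell pairing by number from a difference between numbers 1 and 2 and numbers 3 to 6. With the number as a block edgeR still called 0 genes between GFP and DN. The test was checked on simulated counts with 50 genes changed at each of 4 fold sizes. In DP versus GFP, over 17143 genes, it recovered 0% of genes changed 2-fold, 14% at 4-fold, 64% at 8-fold and 84% at 16-fold, with 3 unchanged genes among 84 called. DESeq2 called 44 unchanged genes among 153 and limma voom 6 among 86 on the same counts. Camera gave adjusted p = 0.00012 for a simulated list of 20 genes changed 2-fold and called 0 of 36 unchanged lists. Apart from the set changes, these counts were drawn from a common mean per gene with edgeR's own dispersions. They held no difference between number sets and no unusual library, so the rates of each tool need not hold for the real data. The counts were also drawn separately for each gene, so this check does not cover lists whose members vary together. Estimated correlations of the real lists reached 0.816 (foamy or TREM2-high macrophages, YFP versus DP).

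Alternatives were DESeq2's median-ratio size factors (RLE) or library size alone in place of TMM, no low-count filter or a stricter one (at least 5 CPM in 3 libraries), DESeq2 1.42.0, limma voom with sample weights, the replicate number as a block, the 2 subsets compared alone, and each library of the subsets compared left out in turn. Added after seeing the data were fits without the 3 libraries that correlated least with the others (DP replicate 5, YFP replicate 5 and YFP replicate 6), without the 4 of DP and DN whose Cx3cr1 and Itgax went against their labels, without these and YFP replicate 6, within numbers 1 and 2, within numbers 3 to 6, and with a term for these number sets. For DESeq2 and limma voom the lists were tested with the form of camera that takes a signed statistic per gene. Up to 100 splits of the same libraries, the real one included, were fitted for each count of genes.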

Results

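RNA was sequenced from 4 subsets of immune cells that had been sorted out of the aorta and carotid arteries of mice with atherosclerosis. The mice lacked Apoe, the gene of a lipoprotein component that clears cholesterol from blood, were 7 months old and had eaten a Western diet for 5 months. They carried GFP as a reporter of Cx3cr1, the fractalkine receptor of monocytes and many macrophages, and YFP as a reporter of Cd11c, the integrin subunit that Itgax encodes in dendritic cells and many tissue macrophages. The subsets are named here by reporter. GFP cells were positive for GFP alone (n = 6), DP cells for both reporters (n = 4), YFP cells for YFP alone (n = 5) and DN cells for neither (n = 3). The series title speaks of macrophage subsets that migrate and that dance in lesions, and each pair of subsets was compared here to ask how their transcripts differ.

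The total gene count per library was 16858501, 11066213, 15831730, 21276913, 21322893 and 21674877 in GFP replicates 1 to 6. It was 10644558, 9790946, 19436572 and 17601365 in DP replicates 1, 2, 4 and 5. In YFP replicates 1, 3, 4, 5 and 6 it was 27742113, 21816285, 17776952, 22549117 and 289166, and in DN replicates 1, 3 and 6 it was 24723544, 14165687 and 15643933. YFP replicate 6 was thus far shallower than the rest. Between 13150 genes (YFP replicate 6) and 21972 genes (DN replicate 1) had at least 1 count. Libraries numbered 1 or 2 held 19245 to 21972 detected genes and those numbered 3 to 6 held 13150 to 18961. The labels do not say whether replicates came from separate mice, so the p-values measure only the spread between these samples, which may be technical.

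Both reporter-driving genes were read first, since they check the labels in part. Cx3cr1 (mm10 chromosome 9, 119901616 to 120069879) averaged 131 ± 30.3 CPM (read counts scaled to a common library size, SD, n = 6) in GFP libraries, 55.2 ± 59.1 in DP (n = 4), 50.5 ± 39.2 in YFP (n = 5) and 93.4 ± 77.5 in DN (n = 3). Itgax (chromosome 7, 128129547 to 128150657) averaged 153 ± 36.3 CPM in GFP, 213 ± 205 in DP, 453 ± 407 in YFP and 214 ± 176 in DN. In YFP replicate 1 Itgax stood at 174.6 CPM, within the range of the GFP libraries (107 to 191). In YFP replicates 3, 4 and 5 it lay above that range (379.7, 498.9 and 1120 CPM). DP replicates 1 and 2 held 92.7 and 118 CPM of Cx3cr1 with 456 and 311 CPM of Itgax, whereas the libraries labelled DP replicates 4 and 5 held 9.43 and 0.427 CPM of Cx3cr1 with 38.6 and 47.8 CPM of Itgax. DN replicate 1 held 4.09 CPM of Cx3cr1 and 11.4 CPM of Itgax, whereas the libraries labelled DN replicates 3 and 6 held 142 and 134 CPM of Cx3cr1 with 332 and 297 CPM of Itgax. These 4 libraries went against their labels, and every direction below that involves DP or DN rests in part on them. The library labelled YFP replicate 6 also did, with Cx3cr1 at 104.5 CPM, within the range of the GFP libraries, and Itgax at 89.56 CPM, below all of them, although these rest on 35 and 30 counts. Apoe (chromosome 7, 19696109 to 19699188), which the mice lack, was listed at 38.4 ± 13.3 CPM in GFP, 15.0 ± 9.60 in DP, 59.2 ± 83.4 in YFP and 21.1 ± 16.1 in DN. None of the 3 genes passed the test in any comparison, with smallest adjusted p of 0.887 for Cx3cr1 and 0.671 for Itgax (both YFP versus GFP) and 0.611 for Apoe (YFP versus DP).

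**Figure D1:**
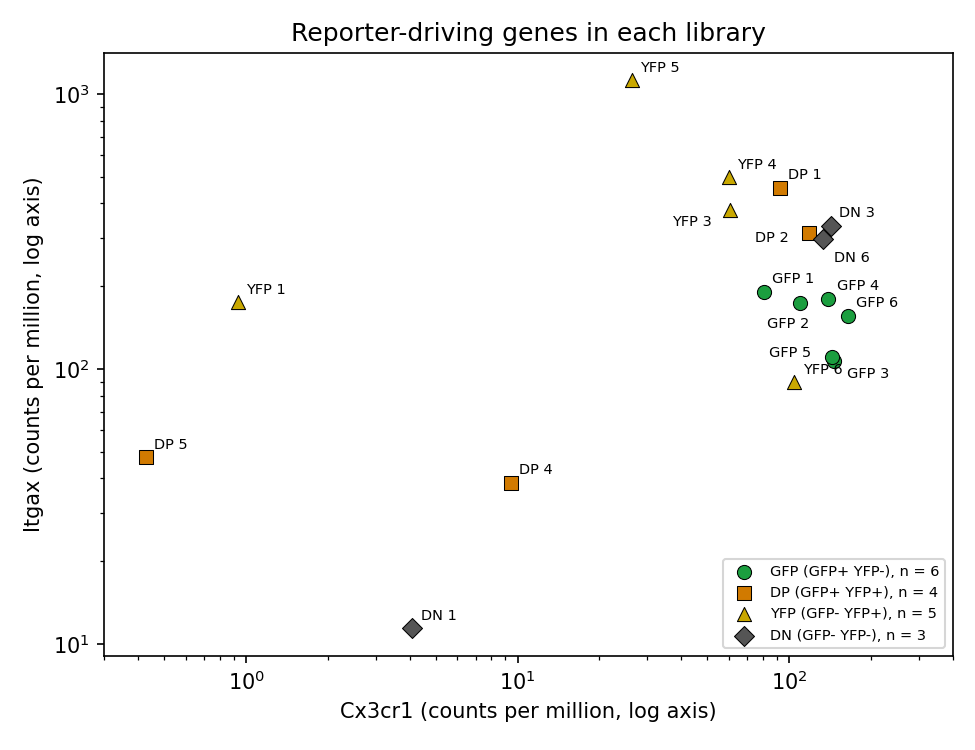
Cx3cr1 (x axis) and Itgax (y axis) in each of the 18 libraries, as CPM on log axes, with the sorted subset as marker shape and colour. The libraries labelled DP replicates 4 and 5 lie near DN replicate 1 at the lower left, and those labelled DN replicates 3 and 6 lie beside DP replicates 1 and 2.

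YFP cells were set against GFP cells to compare the single-positive subsets. Lists of foamy macrophages and of cross-presenting dendritic cells (cDC1) were higher in YFP, and those of inflammatory monocytes and of the interferon response lower, when a small correlation between genes was preset, and none of these 4 passed with an estimated one. The list of lipid uptake and cholesterol handling was not called, with 9 members higher and 13 lower (camera adjusted p = 0.201, and 0.742 with an estimated correlation). Genes induced by tissue dissociation, which read the handling of the tissue, moved too, lower in YFP in 17 of 20 members (median log2 fold change -0.43, camera adjusted p = 0.00138, and 0.362 with an estimated correlation). In the list of foamy or TREM2-high macrophages, 16 of 17 members were higher in YFP, with a median log2 fold change of 1.52. Atp6v0d2, a subunit of the lysosomal proton pump, averaged 533 ± 493 CPM in YFP (SD, n = 5) against 74.6 ± 44.3 in GFP (n = 6), and Cd5l, a macrophage-secreted apoptosis inhibitor, 177 ± 132 against 27.3 ± 33.7. All 13 members of the cDC1 list were higher, with a median of 1.18, among them Itgae, the CD103 integrin, at 39.3 ± 31.9 against 2.08 ± 2.61 CPM, and Clec9a, a receptor for dead cells, at 7.77 ± 10.5 against 0.449 ± 0.539 CPM. In the classical monocyte list 9 of 12 members were lower, with a median of -1.44, and haptoglobin (Hp) stood at 19.5 ± 14.8 against 83.8 ± 29.6 CPM.

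The type I interferon response list was also lower in YFP, in 21 of 25 members with a median of -0.50. The antiviral enzyme gene Oas2 averaged 36.9 ± 11.3 CPM in YFP against 96.0 ± 44.7 in GFP, and Irf7, a transcription factor of that response, 92.4 ± 18.5 against 165 ± 24.0. All 5 tested members of the erythroid and platelet list, of 10 matched entries, were higher in YFP (median 3.93). They were led by Gp1bb and Itga2b, which encode platelet surface receptors, at 16.5 ± 26.5 against 0.276 ± 0.333 CPM and 35.3 ± 40.8 against 1.20 ± 0.992 CPM. All 12 members of the fibroblast list were higher as well (median 2.72), with lumican (Lum) at 454 ± 343 against 69.4 ± 44.9 CPM. Adjusted over the list alone, 10 fibroblast genes, 7 foamy macrophage genes, 4 erythroid and platelet genes and 2 cDC1 genes rose, and none of the monocyte or interferon genes passed.

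Camera, a test of a list against all other genes, called these 6 lists with adjusted p of 1.19e-11 (foamy), 6.92e-05 (cDC1), 7.49e-07 (classical monocyte), 4.15e-05 (interferon), 2.64e-07 (erythroid and platelet) and 1.30e-16 (fibroblast). With an estimated correlation between genes only the erythroid and platelet list held, with adjusted p = 0.0121, against adjusted p = 0.337, 0.224, 0.140, 0.152 and 0.101 with an estimated correlation for the foamy, cDC1, monocyte, interferon and fibroblast lists. All 6 kept their direction and their camera call within replicate numbers 1 and 2 alone and within numbers 3 to 6 alone. Numbers 1 and 2 hold 1 YFP library, assumed to vary like the others, so the values there show its direction and are no replication. The medians in those sets were 0.77 and 1.4 (foamy), 1.36 and 1.16 (cDC1), -1.32 and -1.24 (classical monocyte), -0.60 and -0.51 (interferon), 1.61 and 5.72 (erythroid and platelet) and 4.67 and 1.79 (fibroblast). No single gene passed edgeR's quasi-likelihood test over all genes (0 called, 1203 at an unadjusted p under 0.05), where DESeq2 called 186 and limma voom 448. Without YFP replicate 1, 3 or 6 it called 5, 8 and 11. Over all lists, 14 of 36 were called in this comparison, 8 higher and 6 lower in YFP.

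**Figure D2:**
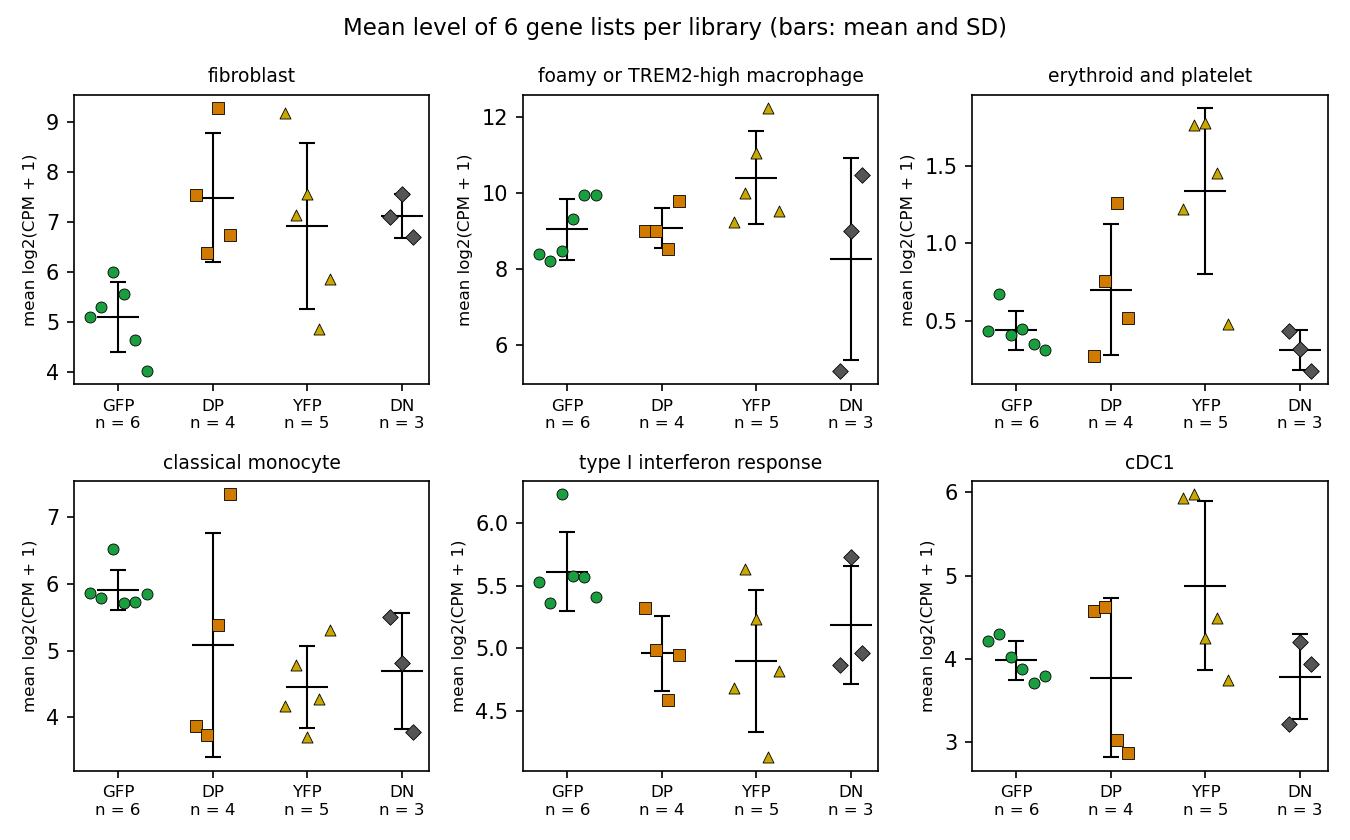
Mean log2(CPM + 1) of the members of 6 gene lists (y axis) in each library, by sorted subset (x axis), with points for libraries and bars for the mean and SD. For the classical monocyte list all 6 GFP libraries lie above all 5 YFP libraries, and the foamy macrophage list reaches its highest level in YFP replicate 5.

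DP cells were set against GFP cells to ask what distinguishes Cx3cr1 reporter cells with the Cd11c reporter. Genes that rose in DP included the fibroblast markers Dcn and Mfap5, of a list whose 12 members were all higher in DP (camera adjusted p = 6.27e-18, and 0.0914 with an estimated correlation). Dcn, which encodes the matrix proteoglycan decorin (chromosome 10, 97479609 to 97518143), averaged 2190 ± 2180 CPM in DP (SD, n = 4) against 139 ± 86.3 in GFP (n = 6), a log2 fold change of 3.98 ± 0.74 (SE, adjusted p = 0.0361). Pcolce, an enhancer of collagen processing (chromosome 5, 137605103 to 137613784), rose by 4.04 ± 0.69 (SE) to 210 ± 195 CPM, and Mfap5, a microfibril component, by 3.91 ± 0.72 to 61.2 ± 61.1 CPM, both at adjusted p = 0.0361. Wnt11 and Sfrp1, a ligand and a secreted inhibitor of Wnt signalling, rose by 3.82 ± 0.74 and 4.72 ± 0.97 (adjusted p = 0.0361 and 0.0437).

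In all, 34 genes rose in DP and 0 fell (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05, with 1172 genes at an unadjusted p under 0.05). The other genes that the naming rule took were Igfbp3, Apod, Hspb8, Ramp2 and Clec11a, with log2 fold changes of 6.63, 6.35, 5.13, 4.84 and 4.53. The highest library was the one labelled DP replicate 5 for 27 of the 34 genes and the one labelled DP replicate 4 for 7, so libraries with little Cx3cr1 and Itgax set these levels. Igfbp3, for example, stood at 198 CPM in DP replicate 4 and at 1.66, 0.895 and 0.747 CPM in DP replicates 1, 2 and 5. The count fell to 0 without any one of the 6 GFP libraries, without DP replicate 4, without DP replicate 5, without the 4 libraries of DP and DN that went against their labels, and with the replicate number as a block. It was 189 without DP replicate 1 and 167 without DP replicate 2. Libraries of the other subsets, which share the fit, moved it as well, to 179, 111, 106, 252 and 21 without YFP replicates 1, 3, 4, 5 and 6, and to 43, 116 and 16 without DN replicates 1, 3 and 6. DESeq2 called 362 genes and limma voom 3451. The voom sample weights were 0.066 in DP replicate 5 and 0.443 in DP replicate 4, against 2.752 and 2.687 in DP replicates 1 and 2. In GFP they were highest in replicates 3 and 4 (4.801 and 5.059). The voom count thus leans on DP libraries numbered 1 and 2 and GFP libraries numbered 3 and 4. It cannot tell the subsets from these number sets.

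**Figure D3:**
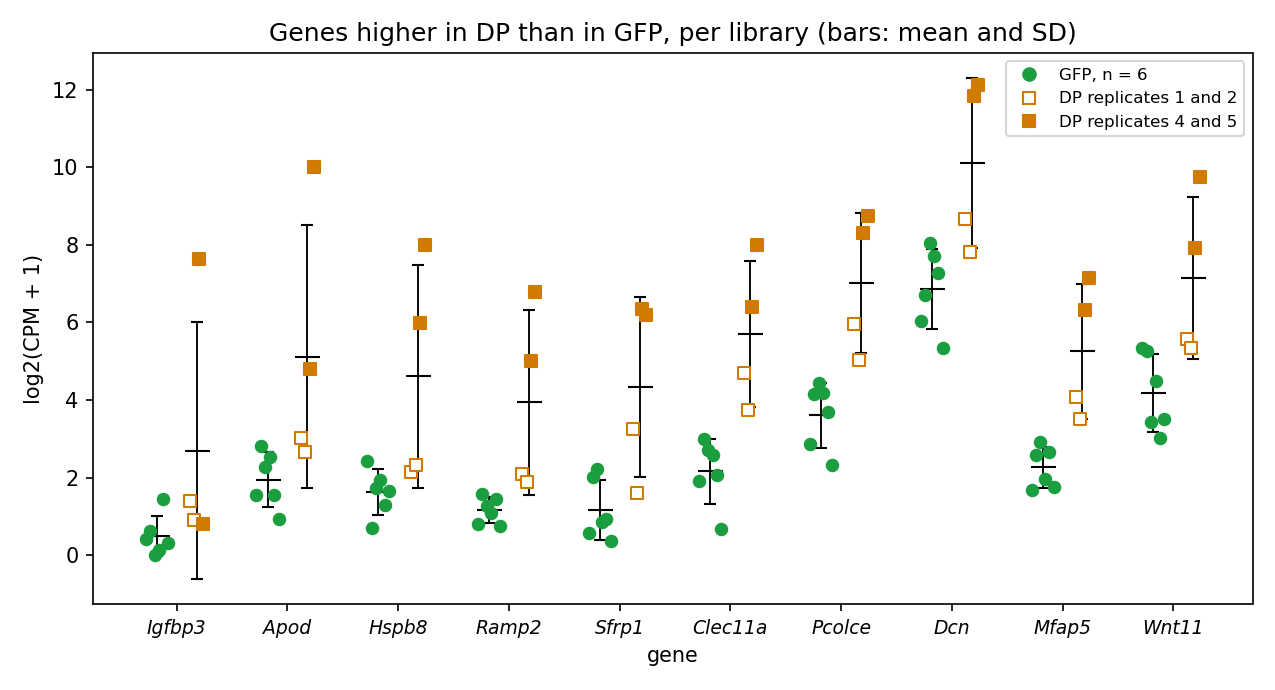
Level of the 10 named genes that rose in DP (x axis) as log2(CPM + 1) (y axis) in the 6 GFP libraries (circles) and the 4 DP libraries (squares, open for replicates 1 and 2), with bars for the mean and SD. The highest value of each gene belongs to the library labelled DP replicate 4 or DP replicate 5.

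Among the lists, the fibroblast list was higher in DP than in GFP in 12 of 12 members, with a median log2 fold change of 3.08. Adjusted over the list alone, 11 of them rose, against 2 over all genes. In camera the list had adjusted p = 6.27e-18, and adjusted p = 0.0914 with an estimated correlation. Its median was 2.0 within numbers 1 and 2 and 3.55 within numbers 3 to 6, so it was higher with and without the libraries labelled DP replicates 4 and 5. The smooth muscle list was higher in 12 of 12 members (median 2.14), with 6 risen when adjusted over the list alone, such as Acta2, smooth muscle actin, at 780 ± 843 CPM in DP against 91.7 ± 60.0 in GFP. The neutrophil list was higher in 13 of 14 members (median 5.52), with 10 risen over the list alone, such as Lcn2, an iron-binding granule protein, at 389 ± 725 against 9.28 ± 8.53 CPM. The camera test gave adjusted p = 6.74e-07 and 7.40e-05 for these lists, and adjusted p = 0.226 and 0.499 with an estimated correlation. Within numbers 1 and 2 the smooth muscle and neutrophil lists turned, with medians of -0.40 and -0.87. The neutrophil list lost its call without DP replicate 5 (adjusted p = 0.352), and without the 4 libraries of DP and DN that went against their labels it was called lower in DP (adjusted p = 0.000126).

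The nonclassical monocyte, interferon response and alternative activation lists were called lower in DP with the preset correlation, and not with an estimated one (adjusted p = 0.101, 0.219 and 0.362). The classical monocyte and resident macrophage lists were not called, with 8 of 12 and 12 of 17 members higher. Camera, which tests a list against all other genes, pointed the other way, to lower in DP, for both. Its adjusted p was 0.0939 and 0.858, and 0.677 and 0.958 with an estimated correlation. The nonclassical monocyte list had 8 of 12 members lower (median -0.31), with 1 fallen and 2 risen over the list alone. The receptor gene Cd300e fell to 2.65 ± 2.75 CPM against 23.5 ± 4.86 in GFP. The interferon response list had 20 of 25 members lower (median -0.44), with Irf7 at 85.8 ± 20.4 against 165 ± 24.0 CPM. The alternative activation list had 10 of 17 members lower with a median of -0.60, although its mean was 0.11. In it Arg1, arginase 1, stood at 2.40 ± 2.28 CPM in DP against 20.3 ± 15.6 in GFP, and Retnla, a secreted product of the same state, at 2240 ± 4320 against 47.1 ± 71.9. Camera gave adjusted p = 0.00489, 0.000424 and 0.00570 for the 3 lists with the preset correlation. The nonclassical monocyte and alternative activation lists lost their call without DP replicate 1 (adjusted p = 0.0685 and 0.0737) and without DP replicate 2 (0.0853 and 0.121). The dissociation list was lower in 16 of 20 members (median -0.29, camera adjusted p = 0.0241, and 0.537 with an estimated correlation). The median over all genes was itself 0.20 in this comparison, and the list values are not corrected for it.

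YFP cells were set against DP cells to compare Cd11c reporter cells without and with the Cx3cr1 reporter. The foamy macrophage list was higher in YFP in 15 of 17 members (median log2 fold change 1.34). In it Gpnmb, a lysosomal glycoprotein gene, averaged 4660 ± 4410 CPM in YFP (SD, n = 5) against 658 ± 206 in DP (n = 4), and Cd5l 177 ± 132 against 20.2 ± 5.48. Both are among 6 members that rose when adjusted over the list alone. The cDC1 list was higher in 12 of 13 members (median 1.32), with Itgae at 39.3 ± 31.9 against 5.33 ± 3.11 CPM. The lysosome list was higher in 21 of 22 members (median 0.67), with the protease gene Ctsl at 2950 ± 3250 against 644 ± 418 CPM. All 5 tested members of the erythroid and platelet list, of 10 matched entries, were higher (median 2.39). The smooth muscle list was lower in 11 of 12 members (median -1.61), with 3 fallen over the list alone, and the neutrophil list in 13 of 14 (median -4.83), with 9 fallen.

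In camera the lists had adjusted p = 1.10e-10 (foamy), 3.82e-07 (cDC1), 5.17e-06 (lysosome), 0.00100 (erythroid and platelet), 2.06e-05 (smooth muscle) and 0.000181 (neutrophil). The adjusted p with an estimated correlation was 0.362, 0.123, 0.564, 0.101, 0.362 and 0.519 in the same order, and 10 of 36 lists were called with the preset one. No gene passed edgeR's test over all genes (0 called, 1154 at an unadjusted p under 0.05), where DESeq2 called 133 and limma voom 0. Within numbers 1 and 2, which hold 1 YFP library, the lysosome and smooth muscle lists turned, with medians of -0.52 and 1.41. YFP replicate 5 held the highest foamy list level, 12.23 against 9.23 to 11.04 in the other YFP libraries and 8.51 to 9.78 in DP. Without it the foamy list kept its call (adjusted p = 0.00109) and the lysosome list lost it (adjusted p = 0.271). The neutrophil list stood at 5.45 and 7.29 in the libraries labelled DP replicates 4 and 5 and at 1.97 and 2.15 in DP replicates 1 and 2. It lost its call without DP replicate 5 (adjusted p = 0.852), and without the 4 libraries of DP and DN that went against their labels it was called higher in YFP (adjusted p = 0.000105). The smooth muscle list lost its call without DP replicate 4 (adjusted p = 0.104).

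GFP cells were set against DN cells, which showed neither reporter. Genes of nonclassical, vessel-patrolling monocytes were higher in GFP, in 10 of 12 list members with a median log2 fold change of 1.03. Treml4, a receptor of these monocytes, averaged 42.2 ± 10.4 CPM in GFP (SD, n = 6) against 7.24 ± 1.14 in DN (n = 3), Emr4 58.2 ± 19.5 against 11.1 ± 9.62, and Cd300e 23.5 ± 4.86 against 3.89 ± 3.01. The fibroblast list was lower in GFP in 12 of 12 members (median -2.08), with 8 fallen when adjusted over the list alone, such as the collagen gene Col3a1 at 165 ± 107 CPM in GFP against 1290 ± 718 in DN. The list of genes induced by tissue dissociation was higher in 19 of 20 members (median 0.43), with the heat shock gene Hspa1a at 2040 ± 266 against 971 ± 440 CPM, and the alternative activation list in 15 of 17 members (median 0.58), with Cd163, a haemoglobin scavenger receptor, at 173 ± 108 against 53.4 ± 45.0 CPM.

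The T cell and the B and plasma cell lists were lower in GFP than in DN, and the macrophage core and resident macrophage lists higher, with the preset correlation and not with an estimated one (adjusted p = 0.232, 0.157, 0.159 and 0.159). The foamy macrophage list was split, with 8 members higher and 9 lower (median -0.13, camera adjusted p = 0.00552 for higher, and 0.731 with an estimated correlation). The T cell list was lower in 19 of 19 members (median -2.90), with the T cell transcription factor gene Tcf7 at 4.67 ± 6.46 against 64.1 ± 107 CPM. The B and plasma cell list was lower in 13 of 14 members (median -4.51), with 9 fallen over the list alone, such as Ms4a1, which encodes CD20, at 1.22 ± 0.399 against 51.6 ± 87.3 CPM. The macrophage core list was higher in 14 of 14 members (median 0.50) and the resident macrophage list in 15 of 17 (median 0.80). DN replicate 1 alone set the lymphocyte levels, with a T cell list level of 6.90 against 2.19 and 1.46 in the libraries labelled DN replicates 3 and 6. Without DN replicate 1 the T cell, B and plasma cell and macrophage core lists turned direction, with adjusted p of 0.121, 0.242 and 0.469, and the resident macrophage and alternative activation lists lost their call (adjusted p = 0.159 and 0.421).

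The camera test gave adjusted p = 2.11e-10 (nonclassical monocyte), 1.67e-38 (fibroblast), 1.36e-12 (dissociation), 1.42e-09 (alternative activation), 1.36e-12 (T cell), 5.92e-12 (B and plasma cell), 1.88e-12 (macrophage core) and 3.43e-11 (resident macrophage). With an estimated correlation the first 4 held, with adjusted p = 0.00106, 0.00840, 0.0303 and 0.0303, and the other lists did not. Of all 20 lists called, the nonclassical monocyte list alone also passed fry, a rotation test of a list's own genes (adjusted p = 0.0407). Of the 84 lists called over all 6 comparisons, 49 were called in the same direction without DN replicate 1, 24 pointed the other way and 5 of these were called that way. No gene passed edgeR's test over all genes (0 called, 231 at an unadjusted p under 0.05), where DESeq2 called 0 and limma voom 3.

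DP cells were set against DN cells, the subsets with both reporters and with none. The smooth muscle list was higher in DP in 12 of 12 members (median log2 fold change 2.20), with 4 risen when adjusted over the list alone, among them Myl9, a myosin light chain gene, at 537 ± 715 CPM in DP (SD, n = 4) against 30 ± 20.6 in DN (n = 3). The mast cell and basophil list was higher in 10 of 11 members (median 6.83), with 7 risen over the list alone, such as the tryptase gene Tpsab1 at 34.5 ± 67.6 against 0.272 ± 0.345 CPM. The endothelial list was higher in 12 of 12 members (median 1.61), with the receptor gene Tie1 at 9.27 ± 14.6 against 0.830 ± 0.723 CPM, and the resident macrophage list in 15 of 17 (median 2.35), with Cbr2 at 761 ± 1280 against 86.4 ± 37.6 CPM. The T cell list was lower in 19 of 19 members (median -2.02), and the NK and cytotoxic list in 13 of 13 (median -3.03), with the perforin gene Prf1 at 0.267 ± 0.310 against 11.4 ± 19.1 CPM.

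Camera gave adjusted p = 1.4e-07 (smooth muscle), 0.000543 (mast cell and basophil), 0.00209 (endothelial), 0.000388 (resident macrophage), 3.96e-05 (T cell) and 0.000611 (NK and cytotoxic). The adjusted p with an estimated correlation was 0.219, 0.394, 0.537, 0.537, 0.537 and 0.564 in the same order, and 12 of 36 lists were called with the preset one. Without the 4 libraries of DP and DN that went against their labels, which leaves 1 DN library, the smooth muscle and mast cell and basophil lists turned, with medians of -0.88 and -0.95, and without DN replicate 1 the T cell and the NK and cytotoxic lists turned (adjusted p = 0.293 and 0.215). The mast cell and basophil list stood at 6.63 in DP replicate 5 and at 0.971 to 1.68 in the other DP libraries, and the resident macrophage list at 9.36 against 4.89 to 7.12. Without DP replicate 5 the former lost its call (adjusted p = 0.366) and the latter turned (adjusted p = 0.795), and limma voom with all libraries called the latter lower in DP (adjusted p = 7.53e-06). The resident macrophage list also lost its call without DN replicate 1 (adjusted p = 0.71), and the endothelial list without DP replicate 4 (adjusted p = 0.462). No gene passed edgeR's test over all genes (0 called, 464 at an unadjusted p under 0.05), where DESeq2 called 30 and limma voom 0.

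YFP cells were set against DN cells to compare GFP-negative cells with and without the Cd11c reporter. The foamy macrophage list was higher in YFP in 17 of 17 members (median log2 fold change 1.45), with the lipid carrier gene Fabp4 at 63.9 ± 78.5 CPM in YFP (SD, n = 5) against 5.86 ± 5.29 in DN (n = 3). The cDC1 list was higher in 13 of 13 members (median 1.33), with Batf3, a transcription factor of these cells, at 33.0 ± 55.8 against 4.11 ± 2.69 CPM. All 5 tested members of the erythroid and platelet list, which has 10 matched entries, were higher (median 4.93). Adjusted over the list alone, 4 rose, among them Gp9, a platelet glycoprotein gene, at 4.38 ± 2.65 against 0.0938 ± 0.106 CPM. Such levels in DN lie near the floor, and in YFP replicate 6 a single count makes 2.99 CPM. The lysosome list was higher in 22 of 22 members (median 0.48) and the macrophage core list in 11 of 14 (median 0.81), with Lyz2, lysozyme, at 26400 ± 27000 against 11800 ± 12800 CPM. The T cell list was lower in 19 of 19 members (median -3.62), with Cd4 at 4.43 ± 3.72 against 24.7 ± 35.1 CPM.

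In camera the lists had adjusted p = 7.22e-18 (foamy), 5.98e-06 (cDC1), 2.40e-09 (erythroid and platelet), 7.19e-07 (lysosome), 4.15e-05 (macrophage core) and 5.60e-09 (T cell), and 14 of 36 lists were called. With an estimated correlation the erythroid and platelet list held, with adjusted p = 0.00840, and the others did not, with adjusted p = 0.159, 0.159, 0.537, 0.519 and 0.406 in the same order. Without DN replicate 1 the lysosome and macrophage core lists turned (adjusted p = 0.316 and 0.271) and the T cell and cDC1 lists lost their call (adjusted p = 0.98 and 0.0547). No gene passed edgeR's test over all genes (0 called, 461 at an unadjusted p under 0.05), where DESeq2 called 12 and limma voom 0.

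Each subset was also set against the mean of the other 3. Genes known from granulocytes were among the 8 genes named for DP. Prg2, which encodes the eosinophil major basic protein (chromosome 2, 84980461 to 84983632), stood at 3370 CPM in the library labelled DP replicate 5, at 33.8 in DP replicate 4 and at 0.166 and 0.814 in DP replicates 1 and 2, a log2 difference of 8.59 ± 1.67 (SE, adjusted p = 0.0208). Ear1 and Ear6, eosinophil ribonucleases, Fcer1a, a chain of the IgE receptor, Il4 and Ldhc peaked in the same library, with log2 differences of 8.43, 8.41, 7.51, 7.34 and 7.00. Elane and Mpo, neutrophil granule enzymes, peaked in the library labelled DP replicate 4 at 156 and 425 CPM, with log2 differences of 7.57 and 6.83. In all, 168 genes were enriched in DP, of which 154 were highest in DP replicate 5 and 14 in DP replicate 4, and the count was 2 without DP replicate 5, and 0 without DN replicate 3, without DN replicate 6 and with the replicate number as a block. It rose to 295 to 354 without DP replicate 1 or 2, GFP replicate 3, 4, 5 or 6 or YFP replicate 3 or 4, to 461 without YFP replicate 1 and to 1229 without YFP replicate 5.

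Genes enriched in YFP numbered 34, all highest in YFP replicate 5. The count was 0 without that library, without DN replicate 3 and with the replicate number as a block, and 5 without DN replicate 1 or 6. It was 14 without GFP replicate 1, 12, 16 and 22 without DP replicates 1, 2 and 5, and 150, 170 and 172 without YFP replicates 1, 3 and 4. They included Nos3, the endothelial nitric oxide synthase (chromosome 5, 24364810 to 24384474), at 207 CPM in that library against 2.52 to 33.0 CPM in the other YFP libraries, a log2 difference of 5.05 ± 0.86 (SE, adjusted p = 0.0116). Ocln, a tight junction protein, stood at 169 CPM there and Cd209e, a C-type lectin, at 132 CPM, with log2 differences of 5.17 and 5.96. The rule also took Chrna5, Trpc4, Dlg2, Slc12a8 and Sept3, with log2 differences of 7.56, 5.75, 5.2, 5.13 and 5.05. For GFP and DN edgeR called 0 enriched genes, with 566 and 214 at an unadjusted p under 0.05, DESeq2 5 and 0, and limma voom 56 and 0. The test of whether the YFP-associated difference was alike in GFP-positive and GFP-negative cells called 0 genes (565 at an unadjusted p under 0.05, DESeq2 12, limma voom 1).

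Genes of actin dynamics, adhesion and motility were tested as a list of 45 members, since the series title concerns cell movement. The list was called in none of the 6 comparisons, with camera adjusted p of 0.403 (DP versus GFP), 0.787 (YFP versus DP), 0.516 (YFP versus GFP), 0.640 (GFP versus DN), 0.604 (DP versus DN) and 0.83 (YFP versus DN). Its median log2 fold changes lay between -0.06 and 0.03. In YFP versus GFP 1 member rose when adjusted over the list alone, and in each other comparison 0 did. Other fixed lists bear on movement too. Matrix proteases and inhibitors were called higher in YFP than in GFP, DN and DP (camera adjusted p = 0.000306, 0.00309 and 0.0299). Against DP 12 of 26 members were higher. Chemokine ligands were called higher in YFP and in GFP than in DN (camera adjusted p = 0.001 and 0.017). None of these calls held with an estimated correlation (adjusted p = 0.219, 0.345, 0.537, 0.362 and 0.537). Chemokine receptors were not called in any comparison.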

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

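The counts of other splits of the libraries were planned before the data were examined. All tests of the explanations weighed below were chosen after the results were seen.

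Values that stood apart from the others of their subset were sought in 123 groups of values of GFP, DP and YFP, and 10 were found, where chance alone gives about 1 in 20. DN, with 3 libraries, was not searched, so DN replicate 1 could not appear here. The groups share libraries and are not independent. Apoe stood at 208 CPM in YFP replicate 5. The classical monocyte and type I interferon response lists had levels, as mean log2(CPM + 1), of 6.52 and 6.23 in GFP replicate 3. The B and plasma cell and endothelial lists stood at 5.65 and 4.13 in YFP replicate 1, and the mast cell and basophil list at 3.20 in YFP replicate 6. The ILC2 list stood at 3.48 in the library labelled DP replicate 4. In the library labelled DP replicate 5 the mast cell and basophil list stood at 6.63 and the proliferation list at 2.19, the latter below its group. The sex-linked list stood at 0.621 in GFP replicate 6, also below its group.

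The first pattern weighed is that Cx3cr1 and Itgax went against the labels in DP replicates 4 and 5 and DN replicates 3 and 6. The log2 ratio of Cx3cr1 to DP replicates 1 and 2, minus that of the macrophage core list, was -2.71 or lower in all 4 pairs. This argues against dilution by cells without the macrophage core genes. Cells that hold those genes but little Cx3cr1 would give the same values, so dilution by them stays open. Cx3cr1 had 4 counts in DP replicate 5, and the transcript loss described below was not weighed here. An exchange of the labels together with their numbers is also argued against, since the Y-linked gene Ddx3y stood at 0.367 CPM in the library labelled DN replicate 6, like the 0.151 CPM of GFP replicate 6, and at 15.4 CPM or more in all libraries numbered 4 or 5. An exchange of the subset names DP and DN within numbers 3 to 6 may account for the pattern, since of 35 splits of these 7 libraries the one that exchanges the 4 called 330 genes and each other split, the real one included, 0. That split also sets DP replicate 5, DN replicate 1 and DP replicate 4, with median correlations with the others of 0.695, 0.869 and 0.879, against libraries at 0.919 to 0.936. It thus cannot tell an exchange from unusual libraries. The macrophage core list, given below, was higher in DP replicates 4 and 5 than in DN replicate 1, which an exchange leaves unexplained. The exchange stays a hypothesis found and tested on the same data. A biological difference, such as loss of reporter gene transcripts in cells that keep the fluorescent protein, was not tested.

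The second pattern is that 154 of 168 genes enriched in DP peaked in DP replicate 5 and all 34 enriched in YFP in YFP replicate 5. Of 3754 genes at 20 CPM or more in all other libraries outside these and YFP replicate 6, 478 were under 2 CPM in DP replicate 5 and 378 in YFP replicate 5, against at most 2 in any other library, so transcripts lost from few cells or little RNA may explain it in part. Granulocytes or mast cells, which a CD45 gate keeps, may add to DP replicate 5, where 20 of 25 members of the neutrophil and the mast cell and basophil lists reached 20 CPM, against at most 15 in another library, with Prg2 at 3370 CPM. Both explanations stay open, and a biological difference between the mice was not tested.

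The third pattern is that libraries numbered 1 or 2 held more detected genes than those numbered 3 to 6. Depth is argued against as the whole cause for the libraries other than YFP replicate 6, since at 9700000 counts the lowest of the 6 held 19067 genes and the highest of the 11 others 17720, a gap of 1347 genes, although at 280000 counts the ranges overlapped (11417 to 13694 genes against 6799 to 13082). For more T cells, 5 of the 6 had a T cell list level no higher than the highest of the others. A single high library can set that bar, so the test cannot decide. DP replicate 4, whose T cell list level is given below, was the library with 17720 genes. NK cells were not tested. A library batch that follows the numbers may account for it. Of 84 splits of the GFP and DN libraries the one that follows the numbers called 3012 genes and each other split, the real one included, 0. That split restates the pattern in the same data, so it cannot tell a batch from a difference between the animals or the cells. The labels name no batch, and a biological difference between the animals was not tested.

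In DP versus GFP 3 of 100 splits, the real one included, called as many genes as the real 34, the highest other calling 46. This small share does not exclude chance as the source of a link to the subset. Every split that called any gene kept the libraries labelled DP replicates 4 and 5 together, and the count was 0 with the replicate number as a block and with a term for the number sets. Among the splits that kept them together others called 40 and 46 genes, so the real count was not unusual there and is not tied to the subset. Chance could not be excluded either for genes enriched in DP (8 of 100 splits, real 168, highest other 2252) or enriched in YFP (13 of 100, real 34, highest other 1812). For the results with a real count of 0 every split was as large, with highest others of 1314 of 100 splits (YFP versus DP), 0 of 100 (YFP versus GFP), 3012 of 84 (GFP versus DN), 330 of 35 (DP versus DN), 0 of 56 (YFP versus DN), 706 of 100 (interaction), 881 of 100 (enriched in GFP) and 2474 of 100 (enriched in DN). Splits that called several times the real count point to a structure of the samples other than their subset labels, such as the replicate numbers and the 4 libraries named above.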

How the results depend on the processing

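Fits without several libraries, within number sets and with a number set term were chosen after seeing the data, and all others were planned. The cause of a change was not tested, except where a setting removes the libraries that held the signal. Counts of genes depended on nearly every choice, while YFP versus GFP kept the direction of its 6 described lists in all settings. Numbers 1 and 2 hold 1 YFP and 1 DN library, and the fits without 4 or 5 libraries that went against their labels hold 1 DN library, each assumed to vary like the others. Simulated changes of 4-fold in DP versus GFP were recovered at 14% with all libraries and at 94% within numbers 1 and 2, with 16 unchanged genes among 174 called there.

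With RLE size factors edgeR called 92 genes in DP versus GFP, 260 enriched in DP and 82 enriched in YFP. These counts, and that of the 26 named genes, were 0 with library size alone. The median log2 fold change of all genes in DP versus GFP was 0.38 with RLE, 0.20 with TMM and 0.15 with library size alone. With no filter the counts were 62 (DP versus GFP), 9 (YFP versus GFP) and 59 (enriched in YFP). The stricter filter gave 62 (enriched in DP), 6 (enriched in YFP) and 16 named genes.

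DESeq2 called 362 genes (DP versus GFP), 133 (YFP versus DP), 186 (YFP versus GFP), 30 (DP versus DN), 12 (YFP versus DN), 12 (interaction), 5 (enriched in GFP), 132 (enriched in YFP) and 13 named genes, and turned the mast cell and basophil list in DP versus DN (adjusted p = 0.976). Limma voom called 3451 (DP versus GFP), 448 (YFP versus GFP), 3 (GFP versus DN), 1 (interaction), 56 (enriched in GFP), 1009 (enriched in DP) and 9 named genes. It turned the neutrophil list in DP versus GFP and YFP versus DP (adjusted p = 0.55 and 0.29) and the resident macrophage list in DP versus DN (adjusted p = 7.53e-06). Its log2 differences turned for Prg2 (-0.03), Ear1 (-1.43), Ear6 (-0.23) and Fcer1a (-0.68) in DP, for Slc12a8 (-2.07) in YFP, and for Ear2 (-1.97), Myl9 (-0.03) and Xaf1 (-0.96) in DP versus GFP. Prg2, Ear1, Ear6 and Fcer1a peaked in DP replicate 5 and Slc12a8 in YFP replicate 5. These libraries had the lowest voom sample weights (0.066 and 0.07).

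With the replicate number as a block the counts of DP versus GFP, of genes enriched in DP and in YFP, and of named genes were 0. In GFP versus DN the block changed no call of the count or of the described lists. Whether the numbers pair libraries is not settled. Of 19 same-numbered pairs 14 correlated above 0.1, and 11 of 18 libraries correlated best with a library of their own number, a hint from the data and not from the design. Ddx3y adds to it, at 0.151 and 0.367 CPM in GFP and DN replicates 6 and at 97.2, 91.0 and 126 CPM in GFP, YFP and DN replicates 3. Xist goes the other way within number 5, at 1.30 CPM in YFP against 19.6 and 21.4 CPM in GFP and DP. Fitting the 2 subsets alone gave 0 in DP versus GFP. With a term for the number sets the counts were 0 (DP versus GFP), 38 (enriched in DP), 13 (enriched in YFP) and 11 named genes.

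Without the 3 libraries that correlated least with the others, the counts were 24 (YFP versus GFP), 13 (enriched in GFP), 0 (enriched in DP), 1 (enriched in YFP) and 3 named genes. The resident macrophage list in DP versus DN turned (adjusted p = 0.733), as did Fcer1a in DP (-1.12) and Dlg2 (-0.10) and Slc12a8 (-1.51) in YFP.

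Without the 4 libraries of DP and DN that went against their labels, the counts were 0 (DP versus GFP, enriched in DP, enriched in YFP and named genes) and 25 (enriched in DN), and 128 lists were called against 84. The neutrophil and smooth muscle lists turned in DP versus GFP (adjusted p = 0.000126 and 0.862) and in YFP versus DP (0.000105 and 0.313), and the mast cell and basophil and smooth muscle lists in DP versus DN (0.0120 and 0.121). In DP the log2 differences turned for Prg2 (-2.41), Ear1 (-4.73), Ear6 (-4.58), Fcer1a (-2.09), Il4 (-0.89) and Ldhc (-0.35), since the libraries that held them were left out. With YFP replicate 6 left out as well, the counts were 55 (YFP versus GFP), 1 (YFP versus DN), 7 (enriched in YFP), 17 (enriched in DN), 127 lists and 0 (DP versus GFP, enriched in DP and named genes). The same 6 lists turned, with adjusted p = 0.00113 and 0.866 (neutrophil and smooth muscle, DP versus GFP), 0.0046 and 0.441 (neutrophil and smooth muscle, YFP versus DP) and 0.00904 and 0.109 (mast cell and basophil and smooth muscle, DP versus DN), as did Prg2 (-1.60), Ear1 (-3.92), Fcer1a (-1.87), Il4 (-0.52) and Ldhc (-0.30) in DP and Myl9 (-0.15) in DP versus GFP.

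Within numbers 1 and 2 the counts were 244 (DP versus GFP), 1496 (YFP versus DP), 1438 (YFP versus GFP), 2296 (GFP versus DN), 2584 (DP versus DN), 1807 (YFP versus DN), 680 (interaction), 43 (enriched in GFP), 16 (enriched in DP), 746 (enriched in YFP), 786 (enriched in DN), 128 lists and 6 named genes. The neutrophil and smooth muscle lists turned in DP versus GFP (adjusted p = 0.00622 and 0.0530), the lysosome and smooth muscle lists in YFP versus DP (0.000985 and 1.94e-05), and the mast cell and basophil and smooth muscle lists in DP versus DN (0.0544 and 0.146). The log2 fold change turned to 4.53 for Cx3cr1, 4.94 for Itgax and 1.36 for Apoe in DP versus DN, to 3.79 for Itgax in GFP versus DN, and to -2.55 for Ccl24 and -0.72 for Myl9 in DP versus GFP. The enriched genes Prg2 (-1.89), Ear1 (-2.51), Fcer1a (-1.20), Il4 (-0.45), Ldhc (-1.30) and Mpo (-0.19) turned in DP and Slc12a8 (-0.55) in YFP. Within numbers 3 to 6 the counts were 188 (DP versus GFP), 9 (YFP versus DP), 1 (DP versus DN), 473 (enriched in DP), 0 (enriched in YFP) and 17 named genes, and the NK and cytotoxic and T cell lists turned in DP versus DN (adjusted p = 0.498 and 0.0288).

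Leaving out each library of the compared subsets in turn gave 0 to 189 genes in DP versus GFP, 0 to 11 in YFP versus GFP, 0 to 1229 enriched in DP, 0 to 172 enriched in YFP and 7 to 24 named genes. The highest values came without DP replicate 1, YFP replicate 6, YFP replicate 5, YFP replicate 4 and either DP replicate 1 or 2. Libraries of the other subsets moved DP versus GFP to between 16 (without DN replicate 6) and 252 (without YFP replicate 5). The adjusted p of lists ranged from 6.97e-16 to 0.242 (B and plasma cell, GFP versus DN), 9.57e-17 to 0.469 (macrophage core, GFP versus DN), 1.34e-15 to 0.121 (T cell, GFP versus DN), 1.62e-10 to 0.215 (NK and cytotoxic, DP versus DN), 7.31e-12 to 0.293 (T cell, DP versus DN), 1.82e-16 to 0.316 (lysosome, YFP versus DN) and 1.50e-10 to 0.271 (macrophage core, YFP versus DN), the highest without DN replicate 1, where these lists turned. For the resident macrophage list in DP versus DN it ranged from 3.75e-08 to 0.795, turned without DP replicate 5. The log2 difference of Fcer1a ranged from -1.33 to 9.20 and that of Slc12a8 from -0.71 to 5.76, turned without DP replicate 5 and without YFP replicate 5. Of the 216 list tests, 6 were called with an estimated correlation and 2 by fry, all in the direction of the preset one.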

Other observations

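Markers of other cell types of the vessel and its blood were spread unevenly over single libraries, given here as list levels, the mean log2(CPM + 1) of the members. The T cell list stood at 6.90 in DN replicate 1 and at 5.01 in the library labelled DP replicate 4, against 2.19 and 1.46 in the libraries labelled DN replicates 3 and 6. The B and plasma cell list stood at 6.88 in DN replicate 1 and at 5.65 in YFP replicate 1. The fibroblast list was highest in the library labelled DP replicate 4 and in YFP replicate 1, at 9.28 and 9.18, although the CD45 gate excludes fibroblasts. Macrophage core genes stood at 5.95 in DN replicate 1 and at 8.47, 9.91, 9.49 and 9.84 in the libraries labelled DP replicates 4 and 5 and DN replicates 3 and 6.

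Genes of the sex chromosomes were alike across subsets within numbers 3 and 6. Ddx3y, on the Y chromosome, stood at 0.151 CPM in GFP replicate 6 and 0.367 in DN replicate 6, and at 97.2, 91.0 and 126 CPM in GFP, YFP and DN replicates 3. Xist, the transcript that silences an X chromosome in females, stood at 4.37, 1.81 and 2.79 CPM in replicates 3 and at 9.43 and 19.7 CPM in GFP and DN replicates 6. Both genes stood above 10 CPM in GFP replicates 1, 2, 4 and 5, DP replicates 1, 2 and 5, YFP replicates 1 and 4 and DN replicate 1, with Xist from 13.2 to 39.4 CPM and Ddx3y from 18 to 87.4 CPM. Xist differed within numbers 4 and 5. It stood at 5.11 CPM in DP replicate 4 against 16.4 and 17.1 CPM in GFP and YFP replicates 4. In YFP replicate 5 it stood at 1.30 CPM, against 19.6 and 21.4 CPM in GFP and DP replicates 5. The labels do not say whether a library pools mice. YFP replicate 6 had 3 counts of Xist and 1 of Ddx3y.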
